A study of Xenopus tropicalis with 9 samples.

How the data were processed

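Libraries of total RNA from tails were made with an Illumina TruSeq RNA kit, per the labels' protocols. Reads were processed with STAR 2.5.4a and featureCounts 1.5.2, per the submitters' processing notes. The genome build is not given in the sources used here, and neither is the strand setting, so overlapping and antisense genes cannot be told apart. The deposited table holds raw counts per Ensembl gene, per the file headers, with gene positions on scaffolds. The authors' 3 deposited tables of selected genes hold mean FPKM per group and the ratio of these means. These FPKM values were checked against the counts, and equal counts divided by the library total and gene length, with no composition factor.

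Samples were grouped by the stage and tissue in the labels: whole tail at stage 60, whole tail at stage 63 and notochord-removed tail at stage 63, with 3 libraries each. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Within each group all pairs of libraries differed by more than sampling noise (chi-square tests over genes with at least 10 counts in the pair). Library totals ran from 26928846 to 34836531 counts.

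Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, estimateDisp, robust glmQLFit and glmQLFTest on all 9 libraries with group means only. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter kept 14125 of 19921 genes. TMM factors were between 0.672 and 0.690 at stage 60 and between 1.18 and 1.25 at stage 63. The counting interval is an exact binomial one and covers counting error only.

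The 24 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule took, per comparison, the 5 largest and 5 smallest log2 fold changes among called genes with a symbol. These needed at least 10 CPM in the higher group and no overlap between groups. It also took up to 3 members per list by p and a fixed set of 13 genes. For genes higher in both, it took the 10 with the largest smaller fold change, under the same limits in both comparisons. Some genes that met the rule are not reported here. Of the fixed set, dio3, col2a1 and shh had no named row to measure. The symbol socs3 is carried by 2 identifiers, and the text gives the one with the larger mean level. Paralogs such as mmp9 and mmp9-th, mmp13 and mmp13l, and the krt5 genes can share reads and are uncertain to that extent.

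Gene names were taken from the authors' tables, which name 6361 genes by symbol, of which 5612 were tested. All but 40 of these come from the stage list, chosen for a ratio above 2. The list test planned over all genes was therefore run within the named genes of that list (camera, preset correlation 0.01, limma 3.58.1; lists of at least 3 members; also with an estimated correlation and with fry), and representation was tested against RefSeq symbols of assembly UCB_Xtro_10.0, used for names only. List symbols were matched by symbol, alias or RefSeq synonym. The first run accepted any synonym and took tenascin C for a troponin; the matching was then restricted to synonyms that are no other gene's symbol, after the list results had been seen. This moved 2 lists of the notochord comparison, leukocyte and endothelium markers, past the threshold, and both versions are reported. In the list tests, 5 lists had fewer than 3 such members. A further 2 lists of early response and heat shock genes were added after the data were seen.

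Alternatives were other scalings, filters, tests (DESeq2 1.42.0, limma-voom), a replicate block, thresholds and leaving out each library. Both comparisons were tested on simulated counts with 200 changed genes each: for the stage comparison 80% of genes changed 1.5-fold and 92% of those changed 2-fold were recovered, with 12 calls among 13849 unchanged genes, and for the notochord comparison 84%, 97% and 9 calls. The changed genes were few and were raised and lowered in equal numbers. The simulation therefore does not test the scaling where most genes change, as in the stage comparison.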

Results

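RNA was measured by sequencing in tails of Xenopus tropicalis tadpoles, a frog whose tail is resorbed during metamorphosis under the control of thyroid hormone. The 9 libraries form 3 groups of 3: whole tails at stage 60, which the submitters place before metamorphosis, whole tails at stage 63, during it, and stage 63 tails from which the notochord, the rod of vacuolated cells along the axis, had been removed. The count table held 19921 genes, and each library held between 26928846 and 34836531 counts assigned to genes. Spearman correlations across genes were between 0.991 and 0.995 within groups. They were between 0.927 and 0.929 between whole tails of the 2 stages. Fold changes below are log2 with their standard error (SE), and expression is given as TMM-normalized CPM, mean ± SD with n = 3 libraries per group. The SE was taken as the fold change divided by the square root of edgeR's F statistic. It is approximate and can be too small for genes with few counts in a group.

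The first comparison asked which genes changed in the whole tail between stage 60 and stage 63. The 5 largest increases among named genes were in mmp9-th, mmp13l, slc6a14.2, krt17 and mmp11. The gelatinase-type metalloproteinase gene mmp9-th rose by 8.96 ± 0.41, from 7.16 ± 5.01 to 3573 ± 153 CPM. Its log2 fold change was 8.64 without stage 60 replicate 2 and 9.71 without stage 60 replicate 1. The collagenase-like mmp13l rose by 7.90 ± 0.18, from 6.90 ± 2.66 to 1648 ± 107 CPM. The stromelysin-3 gene mmp11, a known direct target of thyroid hormone in tadpoles, rose by 6.89 ± 0.12, from 5.73 ± 1.52 to 679 ± 6.75 CPM. The keratin gene krt17 rose by 6.91 ± 0.17 to 1184 ± 46.2 CPM, and the amino acid transporter gene slc6a14.2 by 7.74 ± 0.31, from 0.124 ± 0.123 to 27.4 ± 2.43 CPM. The stage 60 level of slc6a14.2 rested on 7 counts over the 3 libraries. Its log2 fold change was 7.36 without stage 60 replicate 2 and 8.91 without stage 60 replicate 1. Among the named genes that fell, the intermediate filament gene des.2 fell from 1199.7 ± 10.2 to 4.38 ± 0.0927 CPM and vim.2 from 840.2 ± 5.69 to 9.86 ± 0.631 CPM.

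Extracellular proteases rose as a group. Of 31 measured members of the list of matrix metalloproteinases and related proteases, 29 rose, none fell and 2 did not pass, with the same counts when adjusted over the list alone. The membrane-anchored mmp14 rose by 4.43 ± 0.08 to 8409 ± 262 CPM, the collagenase mmp13 by 5.39 ± 0.10 to 921 ± 64.2 CPM, mmp9 by 3.05 ± 0.089 and the fibroblast activation protease gene FAP by 3.11 ± 0.07. Of 8 protease inhibitors, 7 rose, with the metalloproteinase inhibitor timp2 at 3.31 ± 0.085, serpine2 at 3.79 ± 0.079 and spint1 at 2.14 ± 0.068. All 20 measured genes of the thyroid hormone pathway rose, among them the cytosolic hormone-binding protein gene crym (3.11 ± 0.09), the receptor thrb (1.79 ± 0.079) and the direct response genes klf9 (2.54 ± 0.077) and thibz (1.43 ± 0.083). All 46 measured lysosomal genes rose, with acp5 at 2.67 ± 0.084, acp2 at 2.35 ± 0.076 and the sphingolipid activator gene psap at 2.33 ± 0.07. Gene names came only with the authors' selected genes, nearly all of them chosen for a ratio above 2 between these same stages, so the direction of these counts was set by that selection and is not independent evidence.

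Connective tissue, vessel, blood cell and skin genes were also among those that rose. In the list of fibrillar collagens and fibroblast matrix, 36 of 37 rose, with thbs2 at 3.42 ± 0.085, bgn at 3.13 ± 0.07 and col5a1 at 3.06 ± 0.076. All 18 basement membrane genes rose, with col4a2 at 3.73 ± 0.11 and COL17A1 at 2.71 ± 0.086. Of 33 macrophage and leukocyte markers, 31 rose, with the metal transporter slc11a1 at 5.66 ± 0.11 and mpo at 3.64 ± 0.087. All 26 endothelium and vessel markers rose, with cdh5 at 3.35 ± 0.086, esam at 3.32 ± 0.12 and rgs5 at 2.38 ± 0.08. Of 28 epidermis markers, 25 rose, with krt5.2 at 6.56 ± 0.11, dsc3 at 4.60 ± 0.11 and pkp1 at 4.04 ± 0.09. Of 16 apoptosis genes, 15 rose, with bcl2l11 at 2.25 ± 0.079, bax at 2.16 ± 0.099 and CFLAR at 1.43 ± 0.085. The counts of these 6 lists rest on the same selection, and they were unchanged when adjusted over the list alone.

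Lists were also compared by how many of their symbols were named in the authors' stage list and rose. Of 15628 protein-coding RefSeq symbols, 32.4% met this. Against that share, over-representation (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 24 lists) held for lysosomal genes, 46 of 54 symbols (adjusted p = 3.02e-14), and endothelium and vessel markers, 26 of 31 symbols (adjusted p = 2.21e-08). It also held for fibrillar collagens and fibroblast matrix, 34 of 50 symbols (adjusted p = 1.31e-06), metalloproteinases and related proteases, 28 of 39 symbols (adjusted p = 2.54e-06), and the thyroid hormone pathway, 20 of 25 symbols (adjusted p = 3.93e-06). Basement membrane genes, 18 of 22 symbols (adjusted p = 6.04e-06), macrophage and leukocyte markers, 30 of 44 symbols (adjusted p = 5.07e-06), and epidermis markers, 24 of 44 symbols (adjusted p = 0.00575), passed as well. The opposite held for ribosomal proteins, 0 of 74 symbols (adjusted p = 4.79e-12), oxidative phosphorylation, 1 of 74 symbols (adjusted p = 1.12e-10), and sarcomere genes of skeletal muscle, 1 of 62 symbols (adjusted p = 8.24e-09). It also held for proliferation genes, 2 of 41 symbols (adjusted p = 7.29e-05), the proteasome, 2 of 37 symbols (adjusted p = 2.75e-04), and erythrocyte markers, 3 of 27 symbols (adjusted p = 0.0367). A symbol absent from the authors' list can have had a ratio of at most 2, no counts or no matched name, so an absence does not show that a gene fell. The 15628 symbols were not limited to genes measured in tail. Over-representation can therefore come in part from the genes of a list being expressed and named. The remaining 10 lists missed the threshold. Fisher's test counts symbols as independent, so its p-values do not measure the spread between libraries. They can be too small where genes of a list move together.

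All 35 genes with a symbol that fell were named only through the authors' notochord list, so they do not represent the genes that fell. The keratin-like krt18l fell by 7.68 on the log2 scale (SE 0.11), from 199 ± 3.83 to 0.972 ± 0.175 CPM, the creatine synthesis gene gatm from 44.5 ± 2.12 to 0.263 ± 0.127 CPM and the cartilage matrix gene chad from 78.3 ± 5.12 to 0.894 ± 0.233 CPM. The muscle phosphoglycerate mutase gene pgam2 changed by -3.75 ± 0.075 and the myosin light chain gene myl3 by -2.09 ± 0.20; the third measured gene of the sarcomere list, pygm, rose by 0.39 ± 0.13. Of 21 notochord and cartilage matrix genes, 15 rose and 4 fell, the latter named only because they were higher in whole than in notochord-removed tail. They were chad, krt8 (-3.56 ± 0.089), the angiogenesis inhibitor gene cnmd (-3.23 ± 0.079) and the cartilage collagen gene COL9A1 (-3.16 ± 0.096). The notochord transcription factor gene tbxt rose by 0.73 ± 0.16, from 2.46 ± 0.254 to 4.08 ± 0.216 CPM. Most genes that fell, 5723 of 5758, had no symbol; ENSXETG00000024537 (scaffold GL173281.1, 72022 to 74214) changed by -8.26 ± 0.11.

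**Figure D1:**
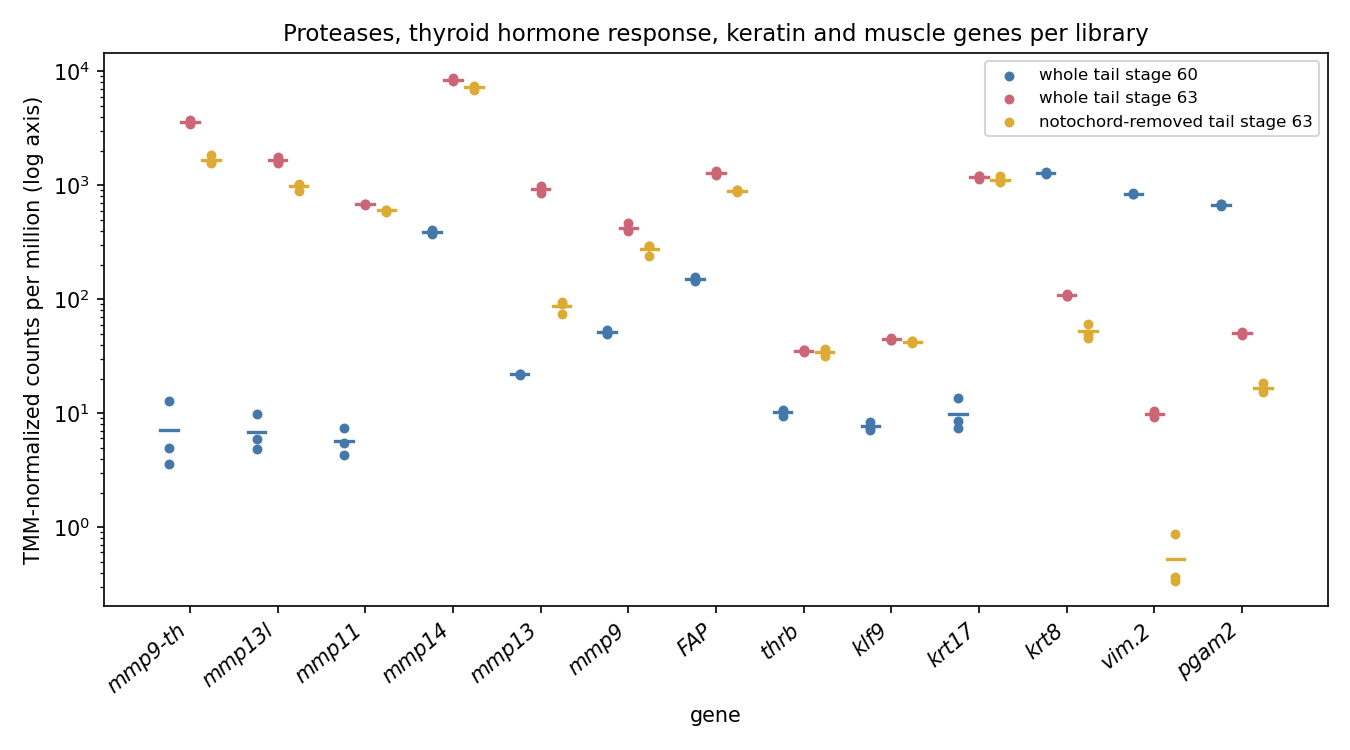
TMM-normalized CPM on a log axis for 13 genes, with each point 1 library and each bar the mean of the 3 libraries of a group. The stage 63 whole tail mean of mmp14 was 8409 CPM against 390.2 CPM at stage 60, and that of krt8 was 108 against 1276 CPM.

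Over the 14125 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05 called 6072 genes higher and 5758 lower at stage 63. At least 2-fold, 3382 were higher and 3055 lower. The adjusted p was 2.26e-07 for mmp9-th, 2.33e-19 for mmp14 and 1.08e-17 for krt8. Groups did not overlap for 85.4% of genes, against 10% by chance. The split depended on scaling: with library size alone 9501 genes were higher and 2821 lower, and the median of all genes moved by 0.82 (log2), to which all stage fold changes here are relative. In a competitive set test (camera) within the 5572 named genes of the authors' stage list, 9 of 19 lists ranked above the rest. The list of spinal cord and neuron markers, of which 11 of 14 members rose, ranked below it (adjusted p = 0.0167), but its median log2 fold change of 1.32 lay above the 1.03 of the named genes, so test and median differ in sign. With an estimated correlation only the metalloproteinase list passed (adjusted p = 0.00258). The other calls were lost, at adjusted p = 0.0739 with an estimated correlation for lysosomal genes, 0.0772 for endothelium, 0.0797 for fibroblast matrix and for protease inhibitors, 0.135 for the thyroid hormone pathway and for epidermis, 0.284 for leukocytes, 0.358 for basement membrane and 0.459 for spinal cord and neuron markers. Apoptosis genes did not stand apart from the other named genes (camera adjusted p = 0.888).

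The second comparison asked which transcripts differed at stage 63 between whole and notochord-removed tail. The collagenase gene mmp13 was at 921 ± 64.2 CPM in whole and 86.6 ± 11.1 CPM in notochord-removed tail (log2 difference, whole minus removed, 3.41 ± 0.089), and the secreted glycoprotein gene olfm4 at 286 ± 23.9 and 23.7 ± 4.26 CPM (3.59 ± 0.11). The receptor gene crhr1.1, for corticotropin-releasing hormone, was 20.7 ± 1.40 CPM in whole and 0.532 ± 0.116 CPM in notochord-removed tail (5.28 ± 0.12). Also higher in whole tail were pgq (2.27 ± 0.11) and pgam2 (1.58 ± 0.075). In the other direction, genes known to respond within minutes to stimulation were higher after notochord removal: socs3 (-2.13 ± 0.073), egr1 (-1.98 ± 0.065), the phosphatase gene dusp1 (-1.69 ± 0.068), IER2 (-1.60 ± 0.073) and the prostaglandin synthase gene ptgs2 (-1.32 ± 0.079). The level of egr1 was 81.7 ± 4.98 CPM in whole and 322 ± 3.02 CPM in notochord-removed tail.

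Known notochord genes check the group labels. Of 21 notochord and cartilage matrix genes, 11 were higher in whole tail, 2 were lower and 8 did not pass, with the same counts adjusted over the list alone. The difference was 3.36 ± 0.20 for tbxt (4.08 ± 0.216 against 0.398 ± 0.170 CPM), 2.87 ± 0.16 for COL9A1, 1.05 ± 0.084 for krt8 and 2.29-fold for cnmd. For chad, 103 counts in whole tail stood against 2 in notochord-removed tail, a ratio of 49.5 with a 95% counting interval from 13.4 to 414. The filament gene vim.2 (4.18 ± 0.17), des.2 (3.16 ± 0.30) and krt18l (1.70 ± 0.25) were higher in whole tail although each was far below its stage 60 level. With single libraries left out, the difference of vim.2 ran from 3.95 without notochord-removed replicate 1 to 4.79 without notochord-removed replicate 3. That of des.2 ran from 2.71 without notochord-removed replicate 2 to 4.26 without notochord-removed replicate 3. Named members outside the stage list were chosen by the authors for this difference, and within the 16 members of the stage list the median was -0.039 while the set test pointed upward without passing (adjusted p = 0.209).

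Some proteases differed between whole and notochord-removed tail. Of 31 metalloproteinases and related proteases, 12 were higher and 1 lower, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00387; adjusted p = 0.484 with an estimated correlation, the highest of its alternatives). The differences were 0.75 ± 0.13 for mmp13l, 0.62 ± 0.08 for mmp9, 0.56 ± 0.07 for mmp3 and 0.52 ± 0.064 for FAP. The difference of mmp14 was 0.22 ± 0.07, which passed at edgeR adjusted p = 0.0238 but not without whole tail replicate 1 or 2 or notochord-removed replicate 1 or 2 (adjusted p at most 0.0691; 3.26e-04 to 0.0691 over all alternatives). That of mmp11 was 0.18 ± 0.083 and did not pass (edgeR adjusted p = 0.127; 0.0215 to 0.248 over the alternatives, the lowest with DESeq2, where it passed). Of 20 thyroid hormone pathway genes, 3 were higher and 1 lower in whole tail, with the same counts adjusted over the list alone and no call of the set (camera adjusted p = 0.821). The lower gene was crym (-0.46 ± 0.068). The genes thrb (0.042 ± 0.066), klf9 (0.081 ± 0.061) and thibz (-0.18 ± 0.068) did not pass; the edgeR adjusted p of thibz was 0.0527 and ran from 0.00720 to 0.199 over the alternatives, passing in 5 of them.

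Markers of other cell types differed between these groups as well. Of 33 macrophage and leukocyte markers, 13 were higher in whole tail and 4 lower, or 17 and 5 adjusted over the list alone, with mpo at 0.87 ± 0.072 and the integrin gene itgb2 at 0.42 ± 0.057. Of 26 endothelium and vessel markers, 1 was higher and 8 lower, or 1 and 10 adjusted over the list alone, with the angiopoietin receptor gene tek at -0.62 ± 0.074, tie1 at -0.45 ± 0.065 and cdh5 at -0.35 ± 0.064; the exception was tagln at 0.77 ± 0.064, a smooth muscle gene. Both lists passed the set test at adjusted p = 0.0369. Both calls were lost in several alternatives, over which the adjusted p ran from 0.00605 to 0.495 for leukocyte and from 0.0136 to 0.484 for endothelium markers. With an estimated correlation the adjusted p was 0.495 for leukocyte and 0.484 for endothelium markers, and with the looser symbol matching that was run first, before it was narrowed for wrong matches, it was 0.130 and 0.0583. Without replicate 3 of the notochord-removed tail it was 0.241 and 0.341, without replicate 1 of the stage 63 whole tail 0.102 and 0.0847, and for endothelium markers without its replicate 2 0.0508. None of the other 16 lists tested passed, among them fibrillar collagens and fibroblast matrix, with 3 higher and 2 lower of 37 and bgn at -0.36 ± 0.064, and apoptosis, with 5 higher and 1 lower of 16 (5 and 2 adjusted over the list alone) and bax at 0.45 ± 0.078.

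**Figure D2:**
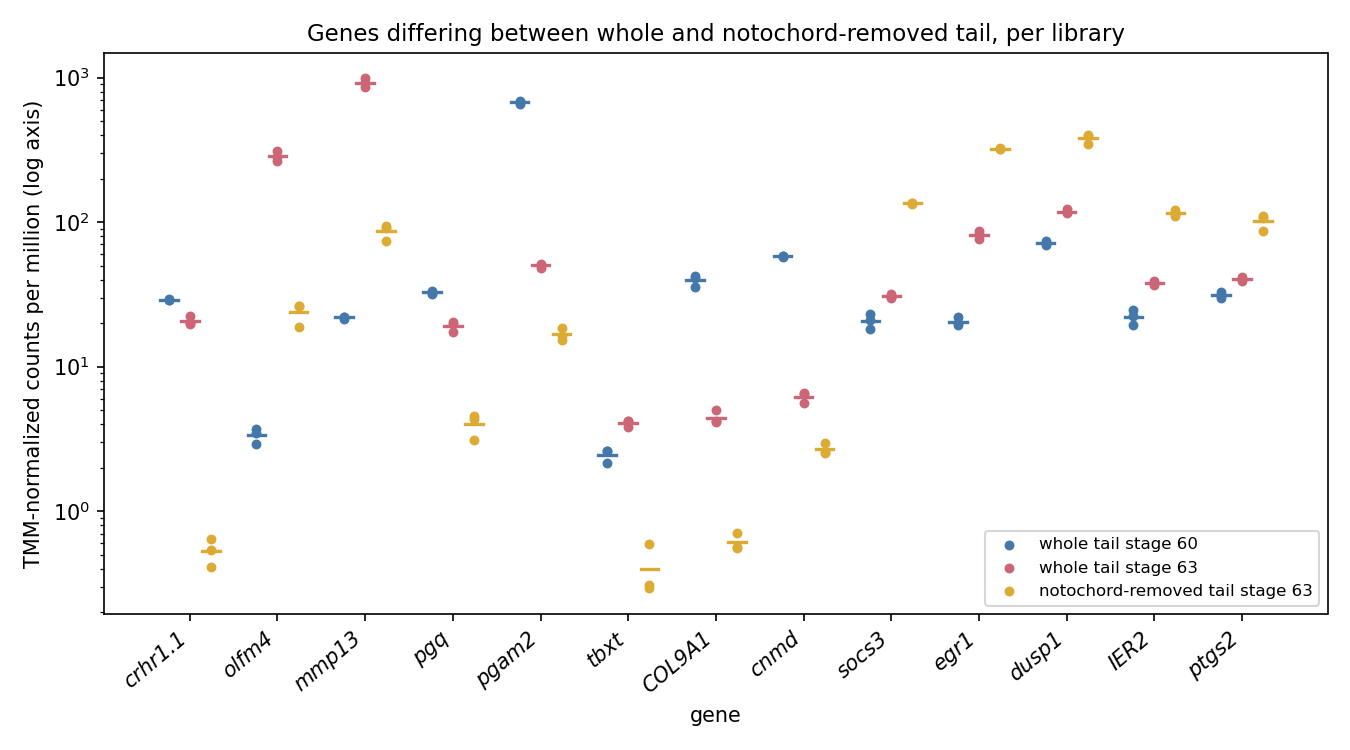
TMM-normalized CPM on a log axis for 13 genes, with each point 1 library and each bar the mean of the 3 libraries of a group. The notochord-removed mean of mmp13 was 86.6 CPM against 921 CPM in whole tail of the same stage, and that of socs3 was 135 against 30.6 CPM.

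Over the same 14125 genes, 1570 were higher and 2043 lower in whole tail, of which 144 and 81 by at least 2-fold. The adjusted p was 9.00e-16 for mmp13, 3.35e-10 for tbxt and 5.61e-14 for egr1. Among genes with no symbol, ENSXETG00000030183 (scaffold GL173464.1, 326290 to 349211) differed by 5.25 ± 0.10 and ENSXETG00000013238 (scaffold GL173025.1, 920062 to 923030) by -4.94 ± 0.10. Without replicate 2 of the stage 63 whole tail, 991 genes were higher.

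The third comparison, the series' subject of notochord during metamorphosis, took genes that were higher at stage 63 and also higher in whole than in notochord-removed tail. Positions are those of the authors' count table, whose genome build is not given in the sources used here. Under the rule for named genes, with its limits on CPM and overlap, the leading genes were mmp13 and olfm4. For mmp13 (ENSXETG00000022190, scaffold GL172755.1, 405836 to 412944) the log2 fold changes were 5.39 for the stage and 3.41 for the notochord. For olfm4 (ENSXETG00000018715, scaffold GL173117.1, 486232 to 493235) they were 6.41 and 3.59. The mineralization-related scppa2 was 32.0-fold and 2.78-fold higher, and avd had log2 fold changes of 1.73 and 1.42. The NADPH oxidase gene nox1 had 2.58 and 0.95, and noxo1.1, whose product organizes that oxidase, had 3.60 and 1.35. The cytochrome oxidase subunit gene cox4i2 (2.63 and 1.08), the arginine synthesis gene ass1 (1.03 and 1.04) and the ectonucleotidase gene nt5e (2.40 and 0.97) followed. For mmp9-th, 2.15-fold higher in whole than in notochord-removed tail, the edgeR call at adjusted p = 0.0266 was lost with DESeq2 (adjusted p = 0.0772). It was also lost without whole tail stage 63 replicate 1, 2 or 3 or notochord-removed replicate 1 or 2 (edgeR adjusted p from 0.0665 to 0.0891), and over all alternatives the adjusted p ran from 2.04e-07 to 0.0891. The stage 63 groups did not overlap, at 3454 to 3746 CPM in whole and 1563 to 1829 CPM in notochord-removed tail, as for 39.3% of genes. The fit took its spread from all 9 libraries, including stage 60, where mmp9-th ran from 3.60 to 12.9 CPM. A fit on only the 6 libraries of this comparison, without stage 60, kept the call. Each fit that left out a single stage 60 library kept it too. These fits also redid the filter and scaling, so the part played by the scatter at stage 60 was not isolated. By contrast, crhr1.1 (-0.49 ± 0.075) and pgq (-0.77 ± 0.092) were lower at stage 63, a direction that turned with library size alone (0.33 and 0.054).

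In all, 981 genes were higher in both comparisons, 66 of them at least 2-fold in each, and 611 without replicate 2 of the stage 63 whole tail. Independent lists would share 675, and 1272 genes were lower in both against 833. Both comparisons use the stage 63 whole tail libraries: in 20 simulations with no effect, 0 genes were higher in both, but these called at most 2 genes in a comparison, so that count bounds nothing. The covariance of fold changes across genes was 0.0970 against 0.0101 simulated, a difference of 0.0869, their correlation 0.164 against 0.427, and the share of the same sign 59.7% against 65.2%. With 3 libraries the shared group does not give both comparisons 2 libraries. Divided as 1 and 2, chosen after seeing the data, so that no library was shared, its 6 divisions gave 286 to 727 genes higher in both, each more than independent lists would share (188 to 528), and covariances of 0.0872 to 0.0994. Fewer libraries also call fewer genes, and part of the excess at 981 may come from sharing.

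**Figure D3:**
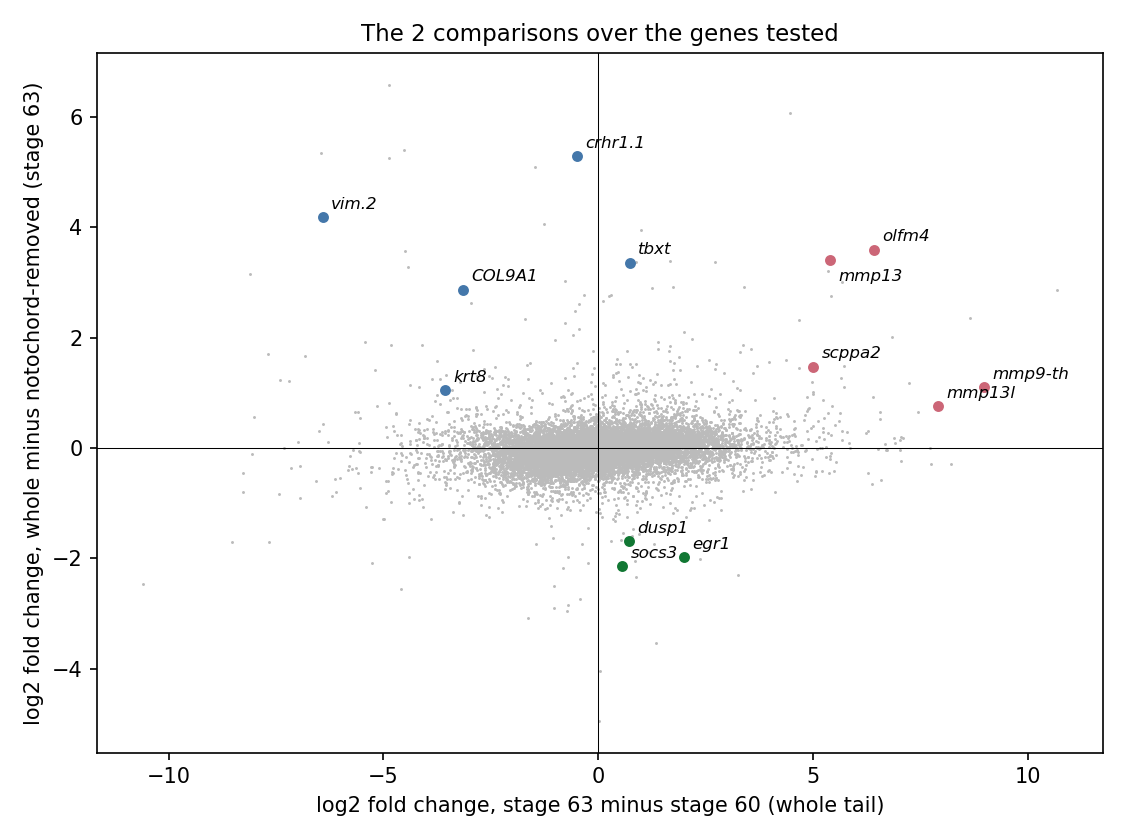
Each grey point is 1 of the 14125 genes tested, with the log2 fold change of stage 63 minus stage 60 on the horizontal axis and that of whole minus notochord-removed tail on the vertical axis. Red marks 5 proteases and other genes high in both, blue 5 genes of the notochord comparison and green 3 early response genes. The point for mmp13 lies at 5.39 and 3.41 and that for socs3 at 0.56 and -2.13.

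The authors' deposited tables list 8054 genes with a ratio above 2 between the stages, 936 between whole and notochord-removed tail, and 630 with both. Of the stage list, 6546 passed the count filter and 6037 of these were called higher. Of the notochord list, 158 passed the filter, 139 of them called higher in whole tail, among them mmp13, olfm4 and crhr1.1. Of the joint list, 88 passed and 74 were called in both comparisons. The median total over the 9 libraries was 6 counts per gene in the notochord list.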

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

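Of 2049 values of 108 gene comparisons under alternatives, 2017 kept direction and call, 23 lost the call, 6 gained it and 3 turned: crhr1.1 (0.33) and pgq (0.054) for the stage with library size only, and thrb for the notochord (-0.013 without notochord-removed replicate 3, the lowest of the left-out libraries, and 0.087 without its replicate 1, the highest), not called either way. Most of these genes were named by rules that favour large fold changes or small p-values, so the 2017 kept values do not describe all genes called. With library size only, 9501 genes were higher and 2821 lower at stage 63, since that scaling lifts the stage fold changes. Of the 11830 stage calls, 8893 were kept with that scaling and 1392 were called in the opposite direction. Of the 3613 notochord calls, 2450 were kept without stage 63 whole tail replicate 2. Stricter thresholds call fewer genes by construction: at least 2-fold left 3382 higher and 3055 lower for the stage, 144 and 81 for the notochord and 66 in both; adjusted p under 0.01 left 789, 1281 and 488 for the last 3. Library size only with at least 2-fold, chosen after seeing the data, gave 6531 higher and 1294 lower for the stage, 137 and 90 for the notochord and 86 in both. Leaving out each library gave 5893 to 6229 and 5612 to 5901 for the stage, 991 to 1939 and 1490 to 2484 for the notochord and 611 to 1220 in both, the last 3 ranges each lowest without stage 63 whole tail replicate 2 and highest without notochord-removed replicate 3; the cause was not tested. With no stage 63 whole tail library shared, chosen after seeing the data, genes higher in both were 529, 286 and 326 with replicate 1, 2 or 3 alone for the notochord, and 577 with replicate 2 alone for the stage; with replicates 1 and 3 there they were 724 and 727.

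Of 38 list tests 13 passed, 1 with an estimated correlation and 31 with fry; of 20 tests of cell type markers 7, 0 and 15. Leaving out each library gave 11 to 13 and 5 to 7. fry asks only whether a set moves on balance, so lists with a downward camera statistic pointed upward for the stage: apoptosis (adjusted p = 5.53e-07), autophagy and ubiquitin ligases (9.13e-09), myogenic regulators (4.32e-06), spinal cord and neuron markers (7.69e-04) and secretory chaperones (3.74e-08). These fry tests used only named genes of the authors' stage list, chosen for a ratio above 2 between the same stages. Their upward direction for the stage was set by that selection and is not independent evidence. With any RefSeq synonym, the matching first run, 11 lists passed. The narrower matching used here was chosen after seeing the data, as was exact symbols only, with 13.

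Replicate numbers are shared between groups, but the labels do not say that they mark shared animals or days. Deviations of same-numbered stage 63 libraries correlated at 0.210, -0.0324 and 0.247. Replicates 1 and 3 each correlated best with their own number, against -0.288 and -0.177 for 1 with 3 across the groups, and replicate 2 did not. The libraries were not treated as pairs, but a shared structure is not excluded. With a replicate block, 6116 genes were higher and 5815 lower at stage 63, 1951 higher and 2253 lower in whole tail, 1221 higher in both, and 13 lists passed; the block ended the notochord call of mmp9-th (adjusted p = 0.0614) and added that of thibz (0.0445). Depth limits genes near 0 counts: 5796 genes were not tested.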

Other observations

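The tests of early response genes and of RNA amount in this part were chosen after the results were seen. The brachyury paralog t2, chosen after its values were seen, stood at 25.7 CPM at stage 60, 9.31 at stage 63 and 0.270 in notochord-removed tail, the difference between stage 63 groups passing edgeR's test at adjusted p = 2.09e-14. The hedgehog ligand gene ihh rose by 4.99 ± 0.31 at stage 63 and was higher in whole tail by 1.01 ± 0.14, also picked after the fact. The gelatinase gene mmp2 rose by 3.72 ± 0.089 and its notochord difference of 0.024 ± 0.08 did not pass; whether this differs from mmp13 was not tested.

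Early response genes were higher in notochord-removed than in whole tail. In a list added after the data were seen, and so not independent evidence, 19 of 37 measured genes were lower in whole tail and 1 was higher (camera adjusted p = 4.81e-47, and 1.15e-05 with an estimated correlation), with junb at -1.12 ± 0.061, jun at -1.09 ± 0.065 and zfp36 at -0.94 ± 0.061. Of the 21 symbols in the added heat shock list only 3 were measured. All 3 were lower in whole tail too, among them hsp70 at -1.17 ± 0.10. Less notochord RNA in the mixture would raise all other genes alike. Of the list, 45.9% lay under -0.5 (exact 95% interval 29.5% to 63.1%), against 4.93% of all genes. The list was picked for lying lower in whole tail, so this share and its interval are not independent evidence. A rise alike for all other genes would still move the list together with most genes. The median log2 difference over all genes was 0.0065, or -0.026 with library size only, against -0.23 for the list. For the 19 members called lower, these values argue against such a rise as the only cause. An earlier developmental state of the notochord-removed tails stays open: 19 of the 36 members that rose at stage 63 were lower in whole tail and 1 was higher, but the list was picked for this, a peak between the stages would give the same, and over all genes higher at stage 63, 981 were higher in whole tail and 533 lower. Handling during dissection and a response of the tissue to losing the notochord both predict a list median below 0, which was -0.23; they cannot be told apart, because every library of 1 group and none of the other had the removal.

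Ratios of FPKM rebuilt from the counts in the manner of the deposited tables put 8054 genes above 2 and 1935 below 0.5 for the stage, while TMM scaling gave near-equal numbers. A candidate explanation is that abundant genes took more of the stage 60 counts. Leaving the 200 most abundant genes out of the totals, which held 63.5% of counts at stage 60 and 47.3% at stage 63, lowered the median log2 ratio from 0.87 to 0.35, which lies between the bounds set beforehand and leaves this open. Without the top 10 genes the median was 0.88, with 15.1% and 15.7% of counts in these, and without 50, 500 and 1000 it was 0.69, 0.27 and 0.24. Genes were ranked by CPM summed over all 9 libraries, most of them from stage 63, so genes abundant only at stage 60 could rank lower. The 10 most abundant genes of each library itself held 17.7% to 18.2% of its counts at stage 60. In whole tails at stage 63 they held 16.2% to 17.4%. A change in RNA amount per tail that is alike for all genes cancels in the library totals, so the difference of log2 TMM factors (0.82) does not bear on it, and RNA amount was not measured.

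Most genes of the deposited notochord list had few counts. Counting noise could fill such a list: the same ratio rule applied to the 9 other splits of the 6 stage 63 libraries gave a median of 722 genes (667 to 760), against 936 for the real split. Among genes that passed the count filter the other splits gave a median of 20.5 and at most 36, against 158; this lies between the bounds set beforehand and leaves open how many of these reflect notochord expression.

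For the stage, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, 6072 higher and 5758 lower against 0 in any other split. For the notochord it was 1 of 10, with 1570 and 2043 against at most 19. With 10 splits a share under 0.05 cannot be reached. For genes higher in both, 2 of 100 partitions of the 9 libraries gave as many as 981. Of the 99 others, 98 called no gene in at least 1 of the comparisons and so could give none, so this test says nothing about chance. The other one gave 5167 genes. Its shared group was the 3 stage 60 libraries, so both of its comparisons set stage 60 against stage 63 libraries. Its count thus holds the stage difference in both comparisons.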
